A study of Homo sapiens with 12 samples.

How the data were processed

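RNA of 12 cultures of HCT116 cells was measured by sequencing, in 6 groups of 2 libraries (mock, siControl, siTotal1, siTotal2, siLong1, siLong2), with groups and replicate numbers taken from the sample titles. Per the labels, cells were seeded at 25000 per well, siRNAs were given at 62.5 nM, cells were collected at 72 h, and libraries were made with a stranded mRNA kit that selects polyadenylated RNA. Per the submitters' processing notes, STAR 2.4.0f1, featureCounts and the hg19 build were used. The annotation release, the strand setting of the counting, any read filter and the version of featureCounts are not given in the sources used here. The deposited values are raw counts of reads per Ensembl gene, 1 column per library, whole numbers with totals of 35604200 to 49746600 reads, and 0 columns belonged to other samples.

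Current symbols were found for 52181 of the 63677 gene identifiers, and 52526 carried a name once GENCODE 29 names were added; 488 tested genes had no symbol. Positions come from GENCODE 29 on GRCh38, matched by identifier, and not from hg19. RefSeq positions are on GRCh38.p14. Where genes overlap on opposite strands (NFYA and OARD1) or have near-identical copies (HSPA1A and HSPA1B, histone genes, mitochondrial genes with nuclear copies), reads could be split or assigned to the wrong member, and their values are uncertain.

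Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 17730. Counts were scaled with TMM and fitted in edgeR 4.0.16 (R 4.3.3) with a quasi-likelihood model of the 6 groups (robust, 6 residual degrees of freedom, common biological coefficient of variation 3.57%). A group mean such as siTotal is the average of its siRNA groups. Contrasts were tested with the quasi-likelihood F-test, and p-values were adjusted by the Benjamini-Hochberg method, with a gene called at an adjusted p under 0.05. Fold changes are on the log2 scale. CPM values are TMM-scaled with the SD over 2 libraries.

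The test was tried on simulated counts for siTotal against siControl (17323 genes, 50 changed genes at each size). It recovered 74% of genes changed 1.2-fold, 94% at 1.5-fold and 100% at 2-fold and at 4-fold, and 13 of its 197 calls were false. Replicates within a group differed by more than counting noise in every group (chi-square per degree of freedom 1.87 to 7.89), so none was treated as a repeat of another. The root mean square log2 difference was 0.135 within groups, 0.383 between siTotal1 and siTotal2, 0.466 between siLong1 and siLong2 and 0.359 between mock and siControl.

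The 28 gene lists cover NF-Y subunits, G2/M cell cycle, G1/S and DNA replication, DNA damage repair, cholesterol synthesis, fatty acid synthesis, endoplasmic reticulum chaperones, the ATF4 and amino acid response, p53 targets, interferon response, inflammatory response, replication-dependent histones, heat shock, apoptosis regulators, glycolysis, purine and one-carbon synthesis, lysosome and autophagy, Wnt and stem cell genes, intestinal differentiation, epithelial junction, mesenchymal and matrix genes, ribosomal proteins, the nuclear respiratory chain, mitochondrial transcripts, RNA interference machinery, and markers of fibroblasts, blood and neural cells. Lists with at least 5 tested members (26) were tested with camera in limma 3.58.1 (preset correlation 0.01), again with an estimated correlation, and with fry, which tests whether genes of a list move on balance in 1 direction. The NF-Y subunits and the blood markers, with 3 tested members each, were not tested as lists, and blood marker values are not reported here. Camera called 3 lists in siTotal against siControl, 10 in siLong against siControl, 10 in siTotal against siLong and 9 in mock against siControl; fry called 15, 22, 17 and 15; and camera with an estimated correlation called 0 in each. In a simulation on 17730 genes for siTotal against siControl, camera found a planted list of 30 genes raised 1.3-fold, and 3 of 200 unchanged lists had p under 0.05. Genes were drawn independently there, so the trial does not cover lists whose genes vary together.

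Named genes followed a rule. Above an average log2 CPM of 1, these were the 6 largest rises and 6 largest falls called in siTotal and in siLong against siControl by the mean and by each siRNA alone, the 5 largest each way in siTotal against siLong, the 3 largest each way in the other comparisons, the 3 NF-Y subunits, and up to 4 members of lists that were called or had at least 3 called members. The rule, the groups, the tests, the lists and the settings listed below were set before the data were examined. OARD1, ADCY10P1 and genes called against both controls were chosen after their values were seen. Some genes that the rule names are not reported here.

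Comparisons that share siControl libraries were set against 20 simulations of unchanged groups and against independent lists. The 7-base word test used 3′ untranslated regions of at least 50 bases of genes with a log2 CPM of at least 1, and words present in at least 50 genes. In a trial with a word lowered by 0.1 in shuffled data, the fitted shift was -0.09 and the word ranked 1. Other settings tried were DESeq2 1.42.0, its median-of-ratios size factors in edgeR, no filter on low counts, a replicate block, fits with only the libraries compared, mock as the control, mock and siControl as 1 control group, each library left out in turn, an estimated correlation for lists and a stricter adjusted p of 0.01 for overlaps. Added after the data were seen were each siRNA sequence as 1 replicate, a test against a 1.5-fold change, libraries thinned to 35604200 reads, and a fit without the libraries labelled siLong2.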

Results

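HCT116, an epithelial line established from a human colon carcinoma, was transfected with siRNAs against NFYA, and polyadenylated RNA was sequenced from stranded libraries. NFYA encodes the sequence-specific subunit of NF-Y, a transcription factor that it forms with the products of NFYB and NFYC and that binds CCAAT boxes in promoters. The 12 libraries fell into 6 groups of 2 libraries: mock (transfection with no siRNA), siControl (a non-targeting siRNA), siTotal1 and siTotal2 (siRNAs to sequence shared by all NFYA transcripts), and siLong1 and siLong2 (siRNAs to the NFYA transcripts with the longest 3′ untranslated region). The siRNAs were used at 62.5 nM and cells were collected 72 h after transfection. Gene counts summed to between 35604200 and 49746600 reads per library, and 17730 of the 63677 listed genes had enough reads to be tested. The design text calls the libraries of a group biological duplicates, so each p-value measures the spread between 2 libraries of a group and not the spread between siRNA sequences, of which there were 2 per target. The question set by the design was which genes depend on the long-untranslated-region form of NFYA and which on NFYA as a whole.

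NFYA reads (ENSG00000001167, chromosome 6, 41072945 to 41099976 on GRCh38, plus strand) were counted first, as the check on the knockdown. The 2 mock libraries held 2783 and 2457 NFYA reads (55.2 and 59.1 CPM) and the siControl libraries 2185 and 2134 (57.4 and 57.5 CPM). NFYA stood at 47.9 and 46.8 CPM in siTotal1, at 46.0 and 46.2 CPM in siTotal2 and at 47.7 and 46.5 CPM in siLong1. In the libraries labelled siLong2 it stood at 69.7 and 70.1 CPM, above every mock and siControl library. Their label names an siRNA to the long NFYA form, which a gene-level count does not measure by itself. Against siControl, NFYA fell by 0.28 on the log2 scale in siTotal1 (SE 0.05, adjusted p = 1.7e-05), by 0.32 in siTotal2 (adjusted p = 1.8e-06) and by 0.29 in siLong1 (adjusted p = 6.9e-06), and rose by 0.28 in the libraries labelled siLong2 (adjusted p = 5.9e-06). The mean of the siLong groups did not differ from siControl (adjusted p = 0.97), since its members moved in opposite directions, and any siLong direction given here is drawn partly from the libraries labelled siLong2. A gene-level count does not separate the long transcript from the others, so the loss of the long form itself was not measured by these values.

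The partner subunits moved with the siTotal siRNAs. NFYB (ENSG00000120837, chromosome 12, 104117077 to 104138289) rose by 0.77 (log2; SE 0.05, adjusted p = 3.5e-15) and NFYC (ENSG00000066136, chromosome 1, 40691648 to 40771603) by 0.72 (SE 0.04, adjusted p = 2.6e-16) in siTotal against siControl, in both siTotal groups and with mock at 0.05 and 0.06. In siLong1, NFYB was at 0.08 (adjusted p = 0.30) and NFYC rose by 0.14 (adjusted p = 0.019). NFYB fell by 0.48 in the libraries labelled siLong2 (adjusted p = 3.0e-08), where NFYC was at 0.05 (adjusted p = 0.47). OARD1, a deacylase gene on the opposite strand whose annotated span (41033627 to 41097787) overlaps NFYA, was chosen after its values were seen: it fell by 0.65 in siLong1 (adjusted p = 7.5e-10) and by 0.64 in the libraries labelled siLong2 (adjusted p = 1.0e-09), and was at -0.05 in siTotal (adjusted p = 0.55). Because the strand setting of the counting is not given in the sources used here, reads of NFYA and OARD1 in the shared interval may not be told apart.

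**Figure D1:**
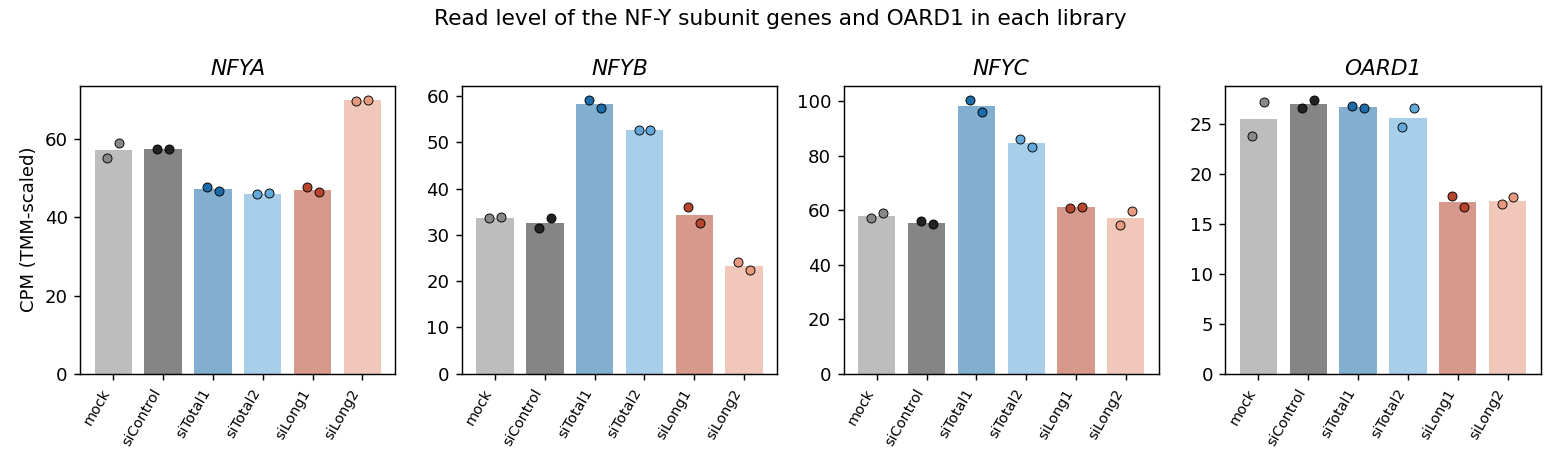
TMM-scaled CPM of NFYA, NFYB, NFYC and OARD1 in each group, with 1 point per library and bars at the group mean. NFYA lies near 47 CPM in siTotal1 and siLong1 and near 70 CPM in the libraries labelled siLong2, against 57.4 and 57.5 CPM in the siControl libraries.

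Both siTotal sequences match coding sequence that the 2 annotated NFYA protein-coding transcripts share. The first sequence in the labels (ACUAGAGGCAGAAGGGAAA) lies at chromosome 6, 41093049 to 41093067 on GRCh38, in exon 8 of 10 of transcript NFYA-201. The second (UGGUGAAGGUGGACGAUUU) lies at 41094443 to 41094461, in exon 9 of the same transcript. The siLong sequences (AGUGAUCAUUGUAGGGUAA and GGUCAUUCCUUUAGCAUCA) matched 0 transcripts of the GENCODE 29 annotation, in which NFYA ends at 41099976, while the RefSeq gene extends to 41102403 on GRCh38.p14. No position is given here for the siLong sites.

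In siTotal against siControl, which asks what changes when all NFYA transcripts are targeted, the cell-surface gene SUSD2, the intermediate filament gene VIM, the axonemal dynein gene DNAH3, the perforin gene PRF1, the adhesion gene CEACAM1 and the protease inhibitor gene SERPINA1 rose most. SUSD2 rose by 2.89 (log2; SE 0.09, adjusted p = 3.1e-23), VIM by 2.79 (SE 0.16), DNAH3 by 2.66 (SE 0.20), PRF1 by 2.47 (SE 0.14), CEACAM1 by 2.37 (SE 0.30) and SERPINA1 by 2.36 (SE 0.20). MYPN, which encodes a sarcomere protein, fell by 2.88 (SE 0.15, adjusted p = 2.0e-18), the G-protein regulator gene RGS2 by 1.87 (SE 0.04), the Wnt antagonist gene DKK1 by 1.74 (SE 0.04), SEC14L1P1 by 1.64 (SE 0.13) and the glucocorticoid-induced gene TSC22D3 by 1.52 (SE 0.08). Most of these moved alike in mock, the transfection without siRNA. Against siControl, mock was higher by 2.69 for SUSD2, 2.07 for VIM and 1.90 for PRF1 and lower for MYPN, at -2.90. DNAH3 (chromosome 16, 20933111 to 21159441) was the exception: 0.612 ± 0.116 CPM in mock, 0.599 ± 0.029 in siControl, 1.52 ± 0.03 in siTotal1 and 9.49 ± 0.58 in siTotal2 (mean ± SD, n = 2 each).

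Across all genes, 7828 differed in siTotal against siControl, 3894 higher and 3934 lower, and 701 of them by at least 2-fold. With mock and siControl as 1 control group 2670 differed, and with mock as the control 2510 of the 7828 kept their call and direction and 915 turned. Of the 26 gene lists tested, fixed before the data were examined, 3 passed. With mock as the control 14 passed, with mock and siControl as 1 group 9 and with DESeq2 values 7. Among 29 tested p53 targets, 19 rose and 5 fell (19 and 5 adjusted over the list alone; adjusted p = 0.0012, and adjusted p = 0.58 with an estimated correlation). Members included TP53INP1 at 2.02, SESN1 at 1.06, GDF15 at 0.85 and TP53I3 at 0.82. Among 26 genes of the ATF4 and amino acid response, which answers amino acid shortage and endoplasmic reticulum stress, 3 rose and 18 fell (3 and 18 adjusted over the list alone; adjusted p = 4.4e-04, and adjusted p = 0.58 with an estimated correlation). Members included ATF3 at -1.35, DDIT3 at -1.12, CHAC1 at -0.94 and DDIT4 at -0.91. Among 20 epithelial junction genes 3 rose and 15 fell (3 and 15 adjusted over the list alone; adjusted p = 1.3e-04, and adjusted p = 0.58 with an estimated correlation). Members included GRHL2 at -0.78, CLDN7 at -0.77, CLDN4 at -0.74 and OCLN at -0.66. With mock as the control the epithelial junction list no longer passed (5 higher and 7 lower, adjusted p = 0.72), and ATF3, OCLN and CLDN4 turned, to 0.63, 0.44 and 0.067. Among the genes with the largest falls, SEC14L1P1, DKK1 and MYPN turned, to 0.54, 0.37 and 0.020. When each siRNA sequence counted as 1 replicate, with mock and siControl as the controls, edgeR called 0 genes in siTotal (smallest adjusted p = 0.66), 423 of 19088 genes had an unadjusted p under 0.05 where chance gives 954, and DESeq2 called 7.

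In siLong against siControl, which asks what changes when the long form is targeted, genes of cell division, DNA replication and DNA repair were lower and p53 targets were higher. G2/M cell cycle genes fell in 42 of 43 members (42 adjusted over the list alone), with 0 higher and a median of -0.41 (adjusted p = 6.5e-14, and adjusted p = 0.38 with an estimated correlation). The centromere histone gene CENPA fell by 0.84 (SE 0.07), the kinesin gene KIF2C by 0.74 (SE 0.03), the centriole kinase gene PLK4 by 0.64 (SE 0.04) and HMMR by 0.63 (SE 0.05). G1/S and DNA replication genes fell in 29 of 37 members and rose in 5 (29 and 5 adjusted over the list alone; median -0.37, adjusted p = 1.0e-06, and adjusted p = 0.59 with an estimated correlation). Among them were RRM2, a subunit gene of ribonucleotide reductase (-0.96), the replication licensing gene CDC6 (-0.85), RFC3 (-0.77) and E2F1 (-0.74). DNA damage repair genes fell in 25 of 27 members and rose in 1 (25 and 2 adjusted over the list alone; median -0.50, adjusted p = 1.3e-07, and adjusted p = 0.26 with an estimated correlation). Members included RAD54B at -0.87, BRCA1 at -0.82 and FANCB at -0.73.

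The p53 targets rose in 22 of 29 members and fell in 4 in siLong against siControl (22 and 4 adjusted over the list alone; median 0.52, adjusted p = 9.1e-07, and adjusted p = 0.36 with an estimated correlation). TP53INP1 rose by 2.90 (SE 0.07), TP53I3 by 2.17 (SE 0.07), the stress cytokine gene GDF15 by 1.70 (SE 0.09) and the antiproliferative gene BTG2 by 1.60 (SE 0.05). The ATF4 and amino acid response list had 19 of 26 members lower and 2 higher (19 and 3 adjusted over the list alone; adjusted p = 2.6e-06, and adjusted p = 0.38 with an estimated correlation). Members that fell included CHAC1 (-1.82), DDIT3 (-1.40), asparagine synthetase ASNS (-1.28) and the cystine transporter gene SLC7A11 (-1.20). Division, repair and p53 lists moved the same way in both siLong groups. G2/M genes were lower in 37 of 43 in siLong1 (38 adjusted over the list alone; median -0.29, adjusted p = 1.1e-07, and adjusted p = 0.70 with an estimated correlation) and in 43 of 43 in the libraries labelled siLong2 (43 adjusted over the list alone; median -0.54, adjusted p = 2.3e-16, and adjusted p = 0.29 with an estimated correlation), although NFYA moved in opposite directions there. They also held with mock as the control: 43 of 43 G2/M genes, 37 of 37 G1/S genes and 24 of 27 repair genes were lower in siLong, and 24 of 29 p53 targets were higher. With an estimated correlation these calls against mock were lost too (adjusted p = 0.21, 0.23, 0.15 and 0.15).

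Other lists also passed in siLong against siControl. Ribosomal protein genes fell in 24 of 35 and rose in 1 (25 and 1 adjusted over the list alone; median -0.13, adjusted p = 0.0013, and adjusted p = 0.65 with an estimated correlation). Members included RPL13A at -0.37 and RPS9 at -0.29. Heat shock genes fell in 12 of 20 and rose in 2 (13 and 2 adjusted over the list alone; adjusted p = 0.018, and adjusted p = 0.65 with an estimated correlation). Members included HSPA1B at -0.86 and HSP90AA1 at -0.41. Wnt and stem cell genes rose in 10 of 18 and fell in 4 (10 and 4 adjusted over the list alone; adjusted p = 0.018, and adjusted p = 0.59 with an estimated correlation), but the call ended with mock as the control (adjusted p = 0.80). SOX4 at 2.09, AXIN2 at 1.83 and SOX9 at 1.70 were among the members that rose against siControl, but AXIN2 turned with mock as the control, to -0.10 (adjusted p = 0.18). DKK1 fell by 2.63. Nuclear genes of the respiratory chain rose in 15 of 31 and fell in 3 (15 and 3 adjusted over the list alone; adjusted p = 0.041, and adjusted p = 0.65 with an estimated correlation). Members included SDHA at 0.39. The list's call also ended with mock as the control (adjusted p = 0.80). Mitochondrially encoded transcripts rose in 4 of 13 and fell in 0 (4 and 0 adjusted over the list alone; adjusted p = 0.0072, and adjusted p = 0.65 with an estimated correlation). Members included MT-ND3 at 0.94. Without the libraries labelled siLong2 the calls of the mitochondrial (adjusted p = 0.11) and respiratory chain (adjusted p = 0.91) lists ended. The share of reads on mitochondrial transcripts was 4.44% ± 0.76 in siControl, 4.20% ± 0.53 in mock, 5.61% ± 0.22 in siLong1 and 6.59% ± 0.015 in the libraries labelled siLong2 (SD, n = 2 each).

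The genes that rose most in siLong against siControl were CEACAM1 at 4.52 (SE 0.23, adjusted p = 2.4e-18), PRF1 at 3.31 (SE 0.13), the filamin-binding gene FBLIM1 at 3.20 (SE 0.18), SUSD2 at 3.15 (SE 0.09), BCL2L15 at 3.13 (SE 0.18) and the transcription factor gene RUNX2 at 3.05 (SE 0.15). CEACAM1 (chromosome 19, 42507304 to 42561234) was near the detection floor in siControl, at 0.267 ± 0.118 CPM, against 0.855 ± 0.255 in mock, 3.41 ± 0.17 in siLong1 and 11.2 ± 0.64 in the libraries labelled siLong2. SUSD2 and PRF1 were also higher in mock against siControl, at 2.69 and 1.90. Mock values of FBLIM1, BCL2L15 and RUNX2 are not reported here. The genes that fell most were DKK1 at -2.63 (SE 0.04), the collagen prolyl hydroxylase gene P3H2 at -2.19 (SE 0.12), the short-chain dehydrogenase gene DHRS2 at -2.08 (SE 0.07), IL31RA at -1.96 (SE 0.14), CHAC1 at -1.82 (SE 0.10) and KIAA0319 at -1.80 (SE 0.14). DKK1 and P3H2 were also lower in mock, at -2.11 and -1.88, and IL31RA turned, to 0.98 in siLong against mock. In total 9494 genes differed, 4450 higher and 5044 lower, and 1181 of them by at least 2-fold. With each siRNA sequence as 1 replicate, edgeR called 1 gene, the mitochondrial ribosomal RNA gene MT-RNR2, at 1.25 (adjusted p = 0.038, 2009 genes at an unadjusted p under 0.05), and DESeq2 called 275.

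The direct test of siTotal against siLong compared siRNAs to all NFYA transcripts, the long form among them, with siRNAs to the long form. In it 10 lists passed. All 43 G2/M genes were higher in siTotal than in siLong (43 adjusted over the list alone; median 0.48, adjusted p = 5.2e-18, and adjusted p = 0.33 with an estimated correlation). Members included HMMR at 0.76, CDC25C at 0.67 and the mitotic kinase gene CDK1 at 0.67. G1/S genes were higher in 34 of 37 and lower in 1 (34 and 1 adjusted over the list alone; adjusted p = 3.4e-13, and adjusted p = 0.34 with an estimated correlation), led by the DNA primase gene PRIM1 at 0.92. DNA repair genes were higher in 21 of 27 (22 adjusted over the list alone; adjusted p = 8.1e-08, and adjusted p = 0.26 with an estimated correlation). Members included BRCA1 at 0.78 and BLM at 0.74. The p53 targets were lower in 21 of 29 and higher in 2 (21 and 2 adjusted over the list alone; adjusted p = 1.8e-06, and adjusted p = 0.33 with an estimated correlation). Members included BTG2 at -1.36, TP53I3 at -1.35 and the cell cycle inhibitor gene CDKN1A at -0.92. Epithelial junction genes were lower in 16 of 20 and higher in 1 (16 and 1 adjusted over the list alone; adjusted p = 6.3e-06, and adjusted p = 0.34 with an estimated correlation). Members included ELF3 at -0.74 and the keratin genes KRT8 at -0.67, KRT19 at -0.58 and KRT18 at -0.52. NFYA itself was lower in siTotal than in siLong by the same test (-0.30, adjusted p = 5.5e-09), a difference carried by the libraries labelled siLong2, without which it was -0.01 (adjusted p = 0.84).

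Further lists differed between siTotal and siLong. ATF4 and amino acid response genes were higher in siTotal in 17 of 26 and lower in 3 (17 and 3 adjusted over the list alone; adjusted p = 0.0020, and adjusted p = 0.46 with an estimated correlation). Members included ASNS at 1.00. Ribosomal protein genes were higher in 22 of 35 (22 adjusted over the list alone; adjusted p = 8.3e-04, and adjusted p = 0.81 with an estimated correlation). Members included RPL4 at 0.30. Apoptosis regulators were lower in 12 of 25 and higher in 4 (12 and 4 adjusted over the list alone; adjusted p = 0.013, and adjusted p = 0.43 with an estimated correlation). Those that moved included genes of opposite action: the pro-apoptotic BIK at -1.03 and APAF1 at -0.50, and the caspase inhibitor gene XIAP at 0.46. Mitochondrial transcripts were lower in 3 of 13 (3 adjusted over the list alone; adjusted p = 0.025, and adjusted p = 0.81 with an estimated correlation) and nuclear respiratory chain genes in 15 of 31 with 2 higher (15 and 2 adjusted over the list alone; adjusted p = 0.033, and adjusted p = 0.81 with an estimated correlation). Without the libraries labelled siLong2 the calls of the mitochondrial (adjusted p = 0.59), respiratory chain (adjusted p = 0.77, median turned to 0.018) and apoptosis (adjusted p = 0.66) lists ended. Mitochondrial reads made up 4.44% in siTotal1 and 5.64% in siTotal2, and 5.61% and 6.59% in the siLong groups.

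DHRS2 (chromosome 14, 23630115 to 23645639) was higher in siTotal by 4.12 (SE 0.05, adjusted p = 5.6e-37), at 34.8 ± 0.89 CPM in siTotal1 and 179 ± 7.3 in siTotal2, against 6.73 ± 0.18 in siLong1, 3.03 ± 0.035 in the libraries labelled siLong2, 14.9 ± 1.1 in mock and 19.2 ± 0.87 in siControl. DNAH3 was higher by 3.20 (SE 0.17), ENSG00000260103 by 3.01 (SE 0.14), the neutrophil chemokine gene CXCL8 by 2.24 (SE 0.13) and the glucose transporter gene SLC2A3 by 1.97 (SE 0.13). Lower were GRIN2C at -2.39 (SE 0.22), CEACAM1 at -2.15 (SE 0.13), BEST1 at -2.08 (SE 0.59, adjusted p = 0.024) and the lipid transporter gene ABCA12 at -1.96 (SE 0.13). In all, 9472 genes differed, 4984 higher and 4488 lower in siTotal, with 654 differing by at least 2-fold. With each siRNA sequence as 1 replicate, edgeR called 0 (1716 genes at an unadjusted p under 0.05, smallest adjusted p = 0.43) and DESeq2 called 137.

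**Figure D2:**
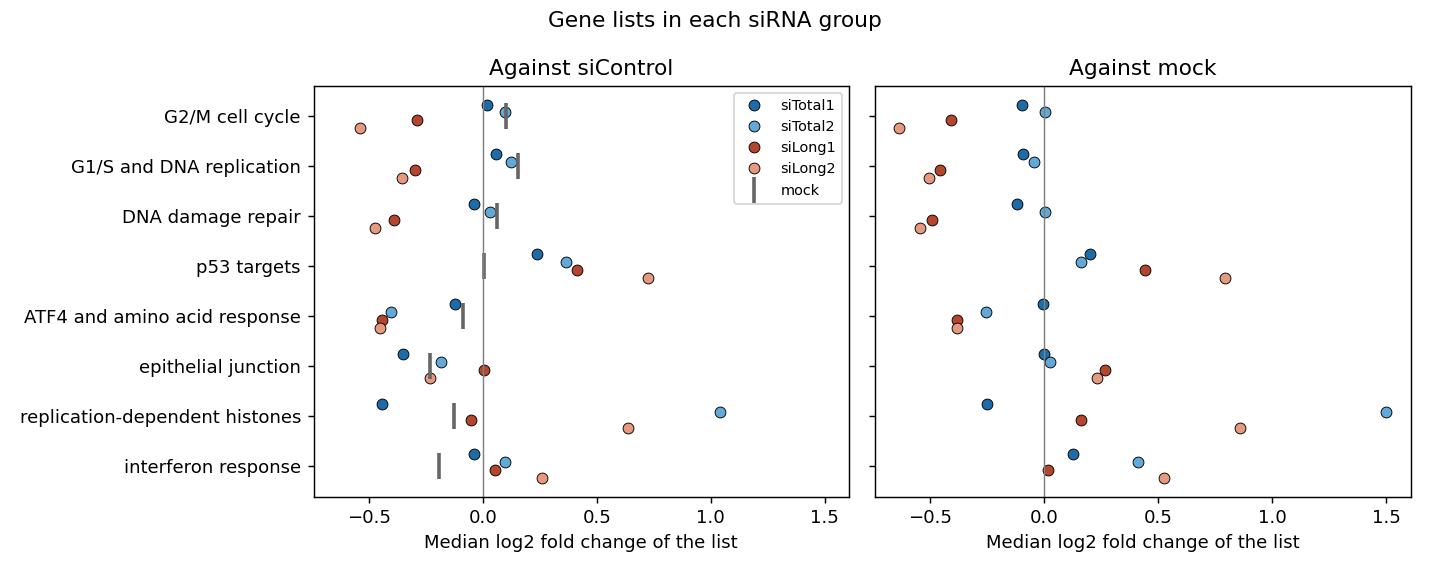
Median log2 fold change of 8 gene lists in each siRNA group against siControl (left, with mock as a grey tick) and against mock (right), 1 point per group. G2/M genes lie at -0.29 in siLong1 and -0.54 in the libraries labelled siLong2 against siControl, and histone genes at 1.04 in siTotal2.

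The siRNAs to a common target also differed from each other. Replication-dependent histone genes, whose messages normally lack a poly(A) tail, were higher in siTotal2 than in siTotal1 in 12 of 14 tested members (12 adjusted over the list alone; median -1.42 for siTotal1 against siTotal2, adjusted p = 8.3e-07, and adjusted p = 0.031 with an estimated correlation). Members included H2AC6 at -2.72 (SE 0.15). Interferon response genes were lower in siTotal1 in 14 of 29 (15 adjusted over the list alone; adjusted p = 8.8e-04, and adjusted p = 0.13 with an estimated correlation), and ribosomal protein genes were higher in 34 of 35 (34 adjusted over the list alone; adjusted p = 1.3e-07, and adjusted p = 0.73 with an estimated correlation). SLC2A3 (2.98, SE 0.16), IL31RA (2.63, SE 0.19) and P3H2 (2.29, SE 0.12) were the genes most above siTotal2 in siTotal1, and MSRB3-AS1 (-2.83, SE 0.19), H2AC6 and SPTSSB (-2.72, SE 0.16) the genes most below. Between siLong1 and the libraries labelled siLong2, G2/M genes were higher in siLong1 in 29 of 43 and lower in 3 (29 and 3 adjusted over the list alone; adjusted p = 1.3e-05, and adjusted p = 0.73 with an estimated correlation) and p53 targets lower in 22 of 29 and higher in 3 (22 and 3 adjusted over the list alone; adjusted p = 1.3e-05, and adjusted p = 0.50 with an estimated correlation). SCG2 (3.10, SE 0.08), the urokinase gene PLAU (2.27, SE 0.05) and CEACAM19 (2.23, SE 0.15) were the genes most above the libraries labelled siLong2 in siLong1, and NLRP4 (-2.99, SE 0.21), PAQR8 (-2.74, SE 0.15) and CFAP92 (-2.73, SE 0.19) the genes most below.

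In counts, 7775 genes differed between siTotal1 and siTotal2 and 9521 between siLong1 and the libraries labelled siLong2. Both siTotal siRNAs called 4120 genes in the same direction against siControl and 753 in opposite directions. Independent lists of these sizes would share 1737 in the same direction, and unchanged groups simulated against the same siControl libraries shared at most 3. Both siLong siRNAs called 5241 genes in the same direction and 1168 in opposite directions, where independent lists would share 2550 and the simulations shared at most 2. The simulations held only the spread between libraries of a group, and not the difference of siControl from mock. Fold changes of siTotal and siLong against siControl correlated across genes (r = 0.67, covariance 0.202), but the simulated unchanged groups gave r = 0.65 with a covariance of 0.028, and 4938 genes were called the same way against 727 opposite, with 2097 for independent lists. With mock and siControl as 1 control group, same-way calls fell to 591 for both siTotal siRNAs, 2677 for both siLong siRNAs and 1346 for siTotal and siLong. With the controls split, siTotal against siControl and siLong against mock had r = 0.03, with 2442 genes called the same way, 2494 opposite and 1989 for independent lists. With siTotal against mock and siLong against siControl, r was 0.03 as well, with 2133 the same way, 1607 opposite and 1453 for independent lists. Split in this manner, siTotal1 against mock and siTotal2 against siControl had r = -0.22 (1578 the same way, 2685 opposite, 1636 for independent lists). For siTotal1 against siControl and siTotal2 against mock r was 0.08 (1564, 1200 and 1031). For the siLong siRNAs r was 0.19 (3629, 2206 and 2429) and 0.13 (3715, 2104 and 2433).

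Mock against siControl compared a non-targeting siRNA with no siRNA, and 7065 genes differed, 3464 higher and 3601 lower in mock, with 636 differing by at least 2-fold. SUSD2 was higher in mock by 2.69 (SE 0.10, adjusted p = 2.1e-21), the calcium-binding protein gene S100A4 by 2.52 (SE 0.07) and VASH2 by 2.14 (SE 0.12). Lower in mock were IL31RA at -2.94 (SE 0.18) and MYPN at -2.90 (SE 0.17). Epithelial junction genes were lower in 13 of 20 and higher in 2 (13 and 2 adjusted over the list alone; adjusted p = 6.9e-04), cholesterol synthesis genes lower in 16 of 25 and higher in 4 (16 and 4 adjusted over the list alone; adjusted p = 0.0078) and apoptosis regulators lower in 12 of 25 and higher in 5 (14 and 6 adjusted over the list alone; adjusted p = 0.043). Higher in mock were G1/S genes in 22 of 37 (23 adjusted over the list alone; adjusted p = 9.1e-04), purine and one-carbon synthesis genes in 14 of 21 (15 adjusted over the list alone; adjusted p = 0.0034) and G2/M genes in 20 of 43 (22 adjusted over the list alone; adjusted p = 0.0044). Wnt and stem cell genes in 11 of 18 (11 adjusted over the list alone; adjusted p = 0.0046), nuclear respiratory chain genes in 16 of 31 (18 adjusted over the list alone; adjusted p = 0.0078) and glycolysis genes in 9 of 20 (9 adjusted over the list alone; adjusted p = 0.027) were also higher. For lists higher in mock, members that were lower are not counted here, and DKK1 of the Wnt list was among them. For each of these 9 lists the adjusted p = 0.67 with an estimated correlation.

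Because siControl differed from mock this widely, genes were also counted against both controls. All 4 NFYA siRNAs called 2125 genes in the same direction against siControl, and 1774 of them were called in that direction in mock as well. All of these comparisons share the siControl libraries, which by itself makes them agree. Called by both siRNAs of a target, in the same direction and against both siControl and mock, were 760 genes for siTotal (435 higher, 325 lower) and 2474 for siLong (1190 higher, 1284 lower), with 245 in common. Both sets rest on the same control libraries, which by itself adds to the 245, and no value for independent lists was computed. The genes named next were chosen after their values were seen. In siTotal they included CXCL8 (2.21, SE 0.16, against siControl), DHRS2 (2.04, SE 0.05) and FN1, the fibronectin gene (0.91, SE 0.05). Lower were the angiogenic factor gene VEGFA (-0.68, SE 0.05) and MGAT4A (-1.10, SE 0.08). In siLong they included BCL2L15, ABCA12 (3.03, SE 0.19), the hemidesmosomal collagen gene COL17A1 (2.14, SE 0.15) and the kallikrein gene KLK10 (2.11, SE 0.08). Lower in siLong were the mitochondrial gluconeogenic gene PCK2 (-1.34, SE 0.07), the linker histone gene H1-10 (-1.59, SE 0.07) and ASNS.

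The remaining 11 tested lists passed in none of the 4 comparisons siTotal against siControl, siLong against siControl, siTotal against siLong and mock against siControl. Mock as the control was not among these 4. There camera called 14 lists in siTotal and 16 in siLong, some of these 11 among them, and 0 in each with an estimated correlation. In siLong against siControl, lysosome and autophagy genes had 15 of 28 higher and 8 lower (adjusted p = 0.080), mesenchymal and matrix genes 9 of 22 higher and 5 lower (adjusted p = 0.096), and interferon response genes 13 of 29 higher and 7 lower (adjusted p = 0.22). Endoplasmic reticulum chaperone genes had 5 of 24 higher and 12 lower (adjusted p = 0.19), fatty acid synthesis genes 4 of 15 higher and 8 lower (adjusted p = 0.22), and inflammatory genes 3 of 17 higher and 8 lower (adjusted p = 0.21). Replication-dependent histones had 4 of 14 higher and 2 lower (adjusted p = 0.21), intestinal differentiation genes 5 of 7 higher and 2 lower (adjusted p = 0.21), and the RNA interference machinery 2 of 14 higher and 4 lower (adjusted p = 0.63). Markers of other cell types did not pass either: 1 of 6 fibroblast markers was higher (adjusted p = 0.32), and 2 of 5 neural markers were higher and 2 lower (adjusted p = 0.46).

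Genes whose 3′ untranslated region carries the 7-base word complementary to positions 2 to 8 of an siRNA guide were compared with genes without it, adjusted for the region's length and GC content, over 11259 genes and 16209 words. The word of the first siTotal sequence (AAGGGAA) was the lowest of all words in siTotal1, with its 2304 genes at a mean of -0.13 relative to others (z = -14.1), and that of the second (GACGATT) was the lowest in siTotal2, with 176 genes at -0.20 (z = -6.82). In siLong1, the word of the first siLong sequence (TAGGGTA) ranked 4 from the lowest (-0.12, z = -6.58), and in the libraries labelled siLong2 the word of the second (TAGCATC) ranked 3 (-0.15, z = -8.62). None of the other sequences' words was among the 10 lowest in any of these groups. The word of the other strand of the second siTotal duplex (CTTCACC) ranked 3 in siTotal2 (z = -5.51), and that of the first siLong duplex (TGATCAC) ranked 47 in siLong1 (z = -3.27). The labels do not say which sequence is number 1, so the match of sequence to group rests on these ranks.

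**Figure D3:**
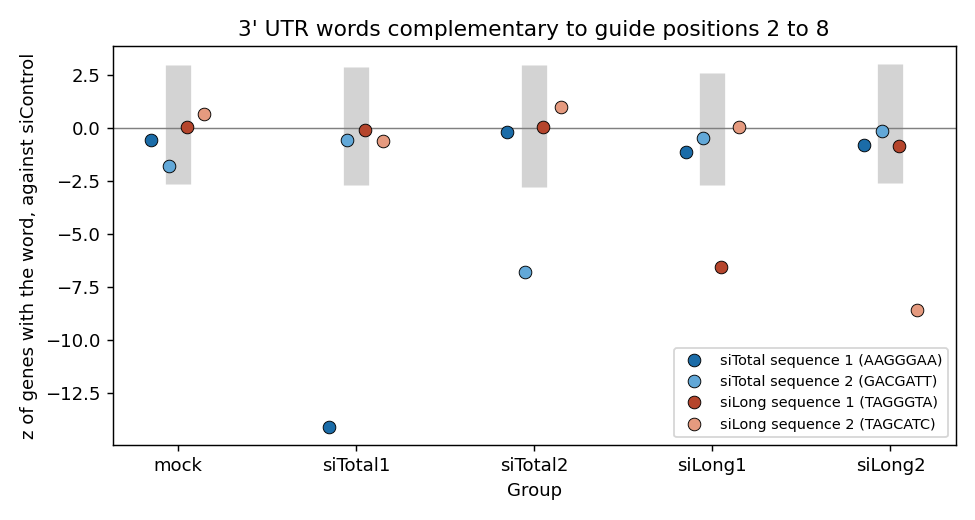
The z value of genes with each guide's 7-base word, in each group against siControl, with grey bars spanning the central 98% of all words. Each siRNA group has a single guide word far below the bar, at z = -14.1 in siTotal1, -6.82 in siTotal2, -6.58 in siLong1 and -8.62 in the libraries labelled siLong2.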

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

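Of the tests in this part, the summed counts for siLong1 against siLong2, the guide words within cell cycle genes, the matched random lists and the other splits of the samples had bounds written before their results were seen; the other tests were chosen after the result was seen.

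NFYA differed between siRNAs to a common target: it was lower in siLong1 than in the libraries labelled siLong2 by -0.57 (log2; adjusted p = 3.3e-12), while NFYB was higher by 0.56 (adjusted p = 1.3e-09). Both stand out because groups that share a target differed in a test of the difference itself. Of the genes that siTotal1 and siTotal2 both called against siControl, 753 went in opposite directions. For siLong1 and the libraries labelled siLong2 this number was 1168. The difference between the siRNAs was called for all of these genes, which opposite calls all but fix in advance. Replication-dependent histone genes had a median of -1.42 in siTotal1 against siTotal2 (adjusted p = 8.3e-07).

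NFYA was higher in the libraries labelled siLong2, although their label names an siRNA to the long NFYA form. Mislabelled libraries, with no siLong siRNA in those labelled siLong2, are argued against by the word of the second siLong sequence, which ranked 3 from the lowest there, while an exchange of the siLong1 and siLong2 labels was not tested, since the sequences are matched to groups by these ranks. The choice of TMM scaling and depth are argued against by NFYA at 0.30 with median-of-ratios size factors and 0.29 with thinned libraries. Both settings kept all 207 values of named genes other than NFYA, so a scaling error that TMM shares with them was not tested. With NFYA, OARD1 and ADCY10P1 summed, siLong1 against siLong2 stayed at -0.41 (SE 0.05, adjusted p = 2.5e-09), which argues against reads moved between these genes as the cause of the whole difference. The rise alone is open: the sum was at 0.026 in siLong2 against siControl (SE 0.05, adjusted p = 0.67), so a move of reads and a rise of NFYA cannot be told apart for these libraries, although OARD1 fell as much in siLong1 (-0.65), where NFYA fell, as in siLong2 (-0.64), which goes against a move of OARD1 reads, and a biological response to loss of the long form was not tested.

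siControl differed from the 5 other groups in the same direction at 1774 genes, which is not the most of any group: the same count was 445 for mock, 1353 and 872 for siTotal1 and siTotal2, 2903 for siLong1 and 2561 for the libraries labelled siLong2. Chance values of the shared siControl libraries, at the spread between libraries of a group, are argued against by 20 simulations. In these at most 2 genes were called the same way in siTotal and siLong. The simulations held no deviation common to both siControl libraries, so such a deviation of the cultures was not tested. Depth is argued against by 6893 calls in mock against siControl with thinned libraries, and a single aberrant library by at least 5578 calls (without siControl replicate 2) with 1 of the 4 left out. A candidate explanation for part of it is pairing of the control siRNA with 3′ untranslated regions: genes with the word CAATACA were lower in siControl than in the other groups (z = -13.9, 950 genes), while the lowest word in mock against the others had z = -3.59. The word was picked as the lowest in these data. It was carried by 174 of 839 genes (20.7%) lower in siControl than in every other group. For those higher in siControl it was 36 of 741 (4.9%), and for all other genes 7.6%. Most genes of the pattern thus lack the word. The sequence of the control siRNA is not given in the sources used here, so it was not compared with this word, and no biological explanation was tested.

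Cell cycle and DNA repair genes were lower in siLong, although the calls of the 3 lists are lost with an estimated correlation (adjusted p = 0.38, 0.59 and 0.26). Direct pairing through the words TAGGGTA and TAGCATC as the whole cause is argued against by the 95 members without either word. Their median was -0.39, and that of the 12 members with a word was -0.52. Members were not screened for the lowest words of these groups, AAGGGTA in siLong1 and AGCATCA in siLong2, so pairing through these stays open. Expression level, length and GC content are argued against by 0% of 10000 matched random lists with a median as low. The random lists were drawn gene by gene, so the 0% does not cover genes that vary together. The siControl libraries as the cause are argued against by mock, against which 99% of the members called lower (95 of 96) were called lower as well. The siTotal siRNAs target the long form too, yet the 3 lists did not pass in siTotal against siControl. All 3 were higher in siTotal than in siLong. This goes against loss of the long form alone as the cause, if siTotal lowered that form as much, which was not measured. Loss of the long NFYA form and effects of the siLong sequences through other genes thus stay open as untested. NFYA counts, which moved in opposite directions in the siLong groups, do not separate the long form.

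With 4 libraries a side there were 35 splits, of which 32 put the libraries of a group on both sides and called 0 genes in edgeR (12 to 1604 at an unadjusted p under 0.05). Only the 3 splits that keep groups whole could call as many as the real one, too few for a share under 0.05. As many genes as in the real split were called in 1 of 35 splits for siTotal against siLong (real 1868, highest other 856), in 1 of 35 for siLong against mock and siControl (real 2669, highest other 485) and in 2 of 35 for siTotal against mock and siControl (real 125, highest other 2110). The last was mock with siTotal2 against siControl with siTotal1, several times the real count. The cause of this was not tested.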

How the results depend on the processing

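The tests with each siRNA sequence as 1 replicate, against a 1.5-fold change, with thinned libraries and without the libraries labelled siLong2 were chosen after seeing the data. The planned search for CCAAT near transcription starts was not run, since no genome sequence was used here.

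Of 207 values of named genes other than NFYA, all kept direction and call with median-of-ratios size factors, thinned libraries and a replicate block, 206 with no filter, 204 with DESeq2 and 204 with only the libraries compared. Of 32 list calls, 30 were kept with DESeq2, 30 with only the libraries compared, 31 with thinned libraries and all with the other 3 of these settings. Leaving out 1 library ended some list calls as well. With a replicate block the counts were 7846 (siTotal), 9524 (siLong), 9498 (siTotal against siLong) and 7098 (mock), with NFYA at -0.30 in siTotal. Residuals of libraries with a common replicate number correlated between groups at r = -0.29 to 0.34, above 0.1 in 6 of 15 pairs. Leaving out 1 library, where the lone library of a group is assumed to vary like the others, gave 6236 to 7887 calls in siTotal, 8042 to 9816 in siLong, 8711 to 9493 in siTotal against siLong and 5578 to 7438 in mock. Leaving out 1 library turned 4 values that had not been far from 0: NFYA in mock (-0.058 to 0.036, turned without mock replicate 1), NFYA in siLong (-0.018 to 4.5e-05, without siLong1 replicate 2), NFYB in siLong1 (-0.012 to 0.14, without siLong1 replicate 1) and NFYC in siLong2 (-0.023 to 0.11, without siLong2 replicate 2).

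The mean NFYA value in siLong was near 0 and changed sign: 0.0070 with median-of-ratios size factors, 6.5e-05 with only the libraries compared, 0.0063 with mock as the control, 0.0017 with mock and siControl as 1 group and 0.0036 with DESeq2. DESeq2 values gave 7 lists in siTotal; the cause was not tested. Camera with an estimated correlation called 0 lists in siTotal, 0 in siLong, 0 in siTotal against siLong and 0 in mock against siControl, where fry called 15, 22, 17 and 15. The wider correlation allowed between genes of a list is the change made.

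With mock as the control, 88 of 120 values of named genes other than NFYA kept direction and call, 14 lost the call and 18 turned. In siTotal, ATF3 turned to 0.63, SEC14L1P1 0.54, OCLN 0.44, DKK1 0.37, GABARAPL1 0.33, HMGCS1 0.10, CLDN4 0.067, MYPN 0.020, GINS1 -0.19, TNRC6B -0.12, ACLY -0.10, SHMT1 -0.039 and TUBB3 -0.0094. In siLong, IL31RA turned to 0.98, VIM -0.36, AXIN2 -0.10, CANX -0.089 and the median of nuclear respiratory chain genes -0.0080, and NFYC in siLong2 to -0.018. Lists called were 14 in siTotal and 16 in siLong, and 0 in each with an estimated correlation (fry called 16 and 20). siTotal2 called 4736 genes, both siTotal siRNAs 1851 the same way, and siTotal and siLong 3074. Of the 7828 siTotal calls, 2510 were kept and 915 turned, and of the 9494 siLong calls 5609 were kept and 808 turned. With mock and siControl as 1 control group, siTotal called 2670, siTotal1 3789 and siTotal2 2206 genes, both siTotal siRNAs 591, both siLong siRNAs 2677, siTotal and siLong 1346, and 9 lists passed in siTotal. Of 120 values of named genes other than NFYA, 81 kept direction and call and 39 lost the call, and of 13 list calls 11 were kept and 2 lost. The difference between mock and siControl adds to the spread in this fit.

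With each siRNA sequence as 1 replicate, edgeR called 0 genes in siTotal, 1 in siLong, 0 in siTotal against siLong and 0 the same way in siTotal and siLong (unadjusted p under 0.05: 423, 2009 and 1716; DESeq2 called 7, 275 and 137), and 8 lists passed in siTotal. NFYA was at -0.29 in siTotal, 0.033 in siLong and -0.33 in siTotal against siLong, without a call. The construction has 2 replicates a group and counts the difference between siRNAs as spread. Against a 1.5-fold change, calls were 567 in siTotal, 1213 in siLong, 580 in siTotal against siLong, 658 in siTotal1, 903 in siTotal2, 1740 in siLong1, 1515 in siLong2, 512 in mock, 653 in siTotal1 against siTotal2 and 1457 in siLong1 against siLong2. Both siTotal siRNAs called 259 genes the same way, both siLong siRNAs 519 and siTotal and siLong 313, since smaller changes no longer count.

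Without the libraries labelled siLong2, NFYA was at -0.29 in siLong and -0.013 in siTotal against siLong, NFYB at 0.077 in siLong, MT-ND2 at 0.11 and MT-ND3 at 0.15 in siTotal against siLong, and the median of nuclear respiratory chain genes at 0.018 there. Of 32 list calls, 27 were kept, 4 were lost and 1 turned, and 8 lists passed in siLong and 8 in siTotal against siLong. Of the 9494 siLong calls 7337 were kept and 152 turned, and of the 9472 in siTotal against siLong 7077 were kept and 227 turned. At an adjusted p under 0.01, both siTotal siRNAs shared 3048 calls, both siLong siRNAs 4129 and siTotal and siLong 3826. Thinned to 35604200 reads, siTotal called 7816 genes and mock 6893.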

Other observations

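The tests and genes in this part were chosen after the result was seen, apart from the test of reversed words.

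Histone and interferon genes stood out in siTotal2 against mock. Replication-dependent histone genes were higher in 10 of 14 (10 adjusted over the list alone; median 1.50, adjusted p = 4.0e-07, and adjusted p = 0.015 with an estimated correlation), and interferon response genes in 21 of 29 (22 adjusted over the list alone; median 0.41, adjusted p = 5.0e-10, and adjusted p = 0.015 with an estimated correlation).

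Mitochondrial RNA genes were called by both siRNAs of each target against both controls. In siTotal against siControl MT-TQ rose by 1.69, MT-TV by 1.51, MT-RNR1 by 1.44 and MT-RNR2 by 0.88. In siLong MT-TQ rose by 1.73, MT-TV by 1.67 and MT-RNR2 by 1.28. Polyadenylated RNA was selected, so these values cover the RNA that passed that selection.

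ADCY10P1, a pseudogene that starts at 41101034 on chromosome 6 and overlaps the end of the RefSeq NFYA gene (41102403), fell by 1.14 in the libraries labelled siLong2 (adjusted p = 8.5e-05) and was at -0.10 in siLong1 (adjusted p = 0.69). The libraries labelled siLong2 held 22 and 46 of its reads and the siControl libraries 82 and 77. It was at -0.70 without siLong2 replicate 1 (adjusted p = 0.022) and at -1.78 without siLong2 replicate 2 (adjusted p = 4.0e-06).

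Already implied by the splits, the difference of mock from siControl resembled that of siTotal2 from siTotal1 (r = 0.32 across 12417 genes). Called the same way in both were 2792 genes and opposite 1254, where independent lists would share 1551. The difference of the libraries labelled siLong2 from siLong1 did not resemble that of mock from siControl (r = 0.0044, 2228 the same way and 2393 opposite, 1897 for independent lists). Against that of siTotal2 from siTotal1 it had r = 0.13, with 2842 the same way, 2310 opposite and 2087 for independent lists. Genes with large changes common to mock against siControl and siTotal2 against siTotal1 were picked as examples. SUSD2 was at 2.69 and 2.42, PRF1 at 1.90 and 1.39, SLC2A3 at -2.04 and -2.98 and KRT7 at -1.53 and -1.24.

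A hypothesis was that each guide lowers transcripts that pair with its positions 2 to 8. In 4 of 4 siRNA groups a word of that target's sequences was among the 10 lowest of all words, and no word of another sequence was, which is consistent with guide pairing with 3′ untranslated regions. The other strand of the duplex may act too in siTotal2, where its word CTTCACC ranked 2 against the other groups (z = -8.81, with -8.86 for the guide's word). Composition of these regions is argued against by the reversed words, the lowest of which ranked 4480 (3 words, since 1 reads the same in both directions).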
